A study of Homo sapiens with 16 samples.

How the data were processed

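RNA was measured in 16 libraries from cultures labelled Huh-7 and HepG2, human hepatoma (liver cancer) cell lines. The cultures were left untreated or exposed to cinobufagin, a cardiotonic steroid of toad venom that inhibits the Na,K-ATPase, at 5 µmol/L for 12 or 24 h. Huh-7 had 3 libraries at each of the 3 times. HepG2 had 3 libraries at 12 h and 3 at 24 h but a single untreated library. Per the labels' protocols, polyadenylated RNA was captured with oligo-dT and sequenced on an Illumina HiSeq 2000.

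The deposited table of each library pairs every gene identifier with an expected count and an FPKM value. Expected counts are RSEM's estimates of the reads that came from a gene, with reads shared between genes divided among them, so 31.1% to 32.3% of the deposited values of a library were not whole numbers. FPKM divides that count by gene length and library size, per the file headers. The submitters' processing notes name HISAT, Bowtie2, RSEM and the hg19 genome build; their versions and settings are not given in the sources used here. The labels' growth protocol also speaks of RPKM and of division by a sample median, and no values of that kind were used here. Each table lists only genes with a value above 0, so an unlisted gene was entered as 0. Gene names came from a table built on GRCh38.p14, which is not the build of the deposited values, so names alone were used and no coordinates are given. Of 16697 identifiers listed in at least 1 library, 16665 were named and 32 were not.

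Total expected counts ran from 9543048 to 10457853 per library, and 3 counts, the upper limit that a count of 0 allows, correspond to 0.287 to 0.314 CPM, the usual scale of counts over the library total. That limit covers counting error only. The labels do not say whether libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Replicate libraries correlated at 0.9918 or higher on log2 CPM, and each pair differed by more than sampling noise, so none was treated as a repeat of another. The biological coefficient of variation was 0.0318.

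Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes with too few counts were removed by filterByExpr, which took out 3064 genes holding 0.023% of the counts and left 13633. Libraries were scaled by TMM, which assumes that most genes keep their level. A quasi-likelihood model with 1 coefficient for each of the 6 groups was fitted over all 16 libraries, leaving 10 residual degrees of freedom. The spread of the lone untreated HepG2 library cannot be estimated and was assumed to equal that of the other groups. Both treated groups were compared with the untreated one and with each other in each line, and the 3 differences of those changes between the lines (HepG2 change minus Huh-7 change) were tested as interactions, giving 9 comparisons. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05 together with a log2 fold change of at least 1, a 2-fold change. Levels are means of CPM on the TMM scale ± SD; levels of cell type markers in untreated cells are CPM without that scaling.

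A set of 31 gene lists was fixed before the data were examined, as were the comparisons, the tests, most alternatives and the rule for named genes. The lists hold Na,K-ATPase subunits, immediate early genes, integrated stress response targets, endoplasmic reticulum chaperones, p53 targets, mitotic genes, DNA replication genes, homologous recombination and checkpoint genes, histone genes, secreted hepatocyte proteins, liver transcription factors, acute phase genes, gluconeogenesis and urea cycle genes, cholesterol synthesis genes, hypoxia and glycolysis genes, NF-kB targets and cytokines, interferon response genes, heat shock genes, NRF2 targets and metallothioneins, BCL2 family genes, mTOR and eIF4E pathway genes, cytosolic ribosomal protein genes, ribosome biogenesis genes, snoRNA host genes, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, osmotic stress genes, Wnt targets, SRF and YAP targets, autophagy and lysosome genes, and markers of cells other than hepatocytes. Each list with at least 3 tested members was compared with all other genes by camera, with the correlation between genes preset at 0.01, and again with a correlation estimated for each list; p-values were adjusted over the 30 lists of a comparison. Of the 13 mitochondrially encoded genes the deposited tables list none, so that list was not tested. Of the 18 snoRNA host genes 15 were listed in no library, and no listed identifier was matched to a noncoding transcript. The snoRNA host list therefore tests 3 genes and says little about host genes as a class.

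The rule for named genes took, in each comparison, the 5 highest and 5 lowest called genes with a mean of at least 10 CPM and no overlap between the groups' libraries (the last condition did not apply to line differences), up to 3 called members of each list in the comparisons with untreated cells, and 15 fixed genes. Not every gene that the rule took is given in the text. Members named outside that rule, most of them where a list had 5 or fewer called genes in a direction, were chosen after their values were seen. Where a list's call at the preset correlation was lost, the p with an estimated correlation is given beside it. Calls given without one held with an estimated correlation. Their printed camera p-values come from the preset correlation and can be far smaller than those with an estimated one. The size of a preset p is therefore no measure of the strength of a call.

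The steps were tested on simulated counts for 13633 genes, of which 200 were changed by log2 1.5 or 3. In each of the 9 comparisons edgeR recovered 100% of the changed genes of either size, gave 0 of them the wrong sign, and called at most 7 unchanged genes (the line difference at 24 h). Camera passed the list of changed genes in 9 of 9 simulated comparisons, at either kind of correlation. The simulated genes varied independently of each other, so this cannot show how the preset and the estimated correlation differ on real data. The simulation is milder than the data, where 36.3% to 44.6% of tested genes were called against untreated cells. With 200 changed genes it cannot show how TMM scaling performs where so many genes change. It cannot test the unknown spread of the lone untreated HepG2 library either.

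The alternatives were RLE, upper-quartile, library-median and plain library-size scaling; no filter or a filter of 1 CPM in 3 libraries; DESeq2 1.42.0; limma on log2(FPKM + 1) with a mean FPKM of at least 1, the same with a pseudocount of 0.1 or without the filter; fits on the libraries of 1 line or of the compared groups; the replicate number as a block; no fold threshold; each library left out in turn; and, for lists, fry, which tests a list against no change where camera compares it with all other genes. An assumed coefficient of variation of 0.2 was added after the data were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 read the tables and drew the figures.

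Against TMM, plain library-size scaling moved the median log2 change of all genes by -0.416, -0.351, -0.399 and -0.267 (Huh-7 at 12 and 24 h, then HepG2 at 12 and 24 h, each against untreated cells). Upper-quartile scaling moved it by -0.27, -0.278, -0.18 and -0.137, and division by the library median by 0.187, 0.101, 0.214 and 0.126. Changes smaller than these shifts depend on the scaling.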

Results

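Gene expression was compared between untreated Huh-7 and HepG2 hepatoma cultures and cultures given cinobufagin at 5 µmol/L for 12 or 24 h, to find which transcripts respond to this Na,K-ATPase inhibitor and whether the lines respond alike. The 16 libraries held 9543048 to 10457853 expected counts each. The untreated Huh-7 libraries listed 14833.67 ± 38.99 genes (SD, n = 3), and the treated ones fewer: 14110.33 ± 28.11 at 12 h and 14088.33 ± 13.65 at 24 h. HepG2 went from 14626 genes in its lone untreated library to 14020.67 ± 19.4 at 12 h and 14065 ± 24.76 at 24 h. A large part of the transcriptome differed between treated and untreated libraries in both lines. Of 13633 tested genes, 5976 (43.8%) and 6083 (44.6%) were called in Huh-7 at 12 and 24 h, and 5151 (37.8%) and 4946 (36.3%) in HepG2. Words such as raised, rose or fell describe these differences, in which drug and culture time are not separated. Below, levels are CPM ± SD with n = 3, except those of untreated HepG2, which come from 1 library without an SD, and counts of higher or lower genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Counts of called list members adjusted over the list alone equalled those over all genes for every list and comparison whose counts are given, and they are given once. Genes said to change most, or to lead a list, do so among called genes with a mean of at least 10 CPM over the compared libraries and, for single genes, no overlap between groups; scarcer genes can have larger folds.

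**Figure D1:**
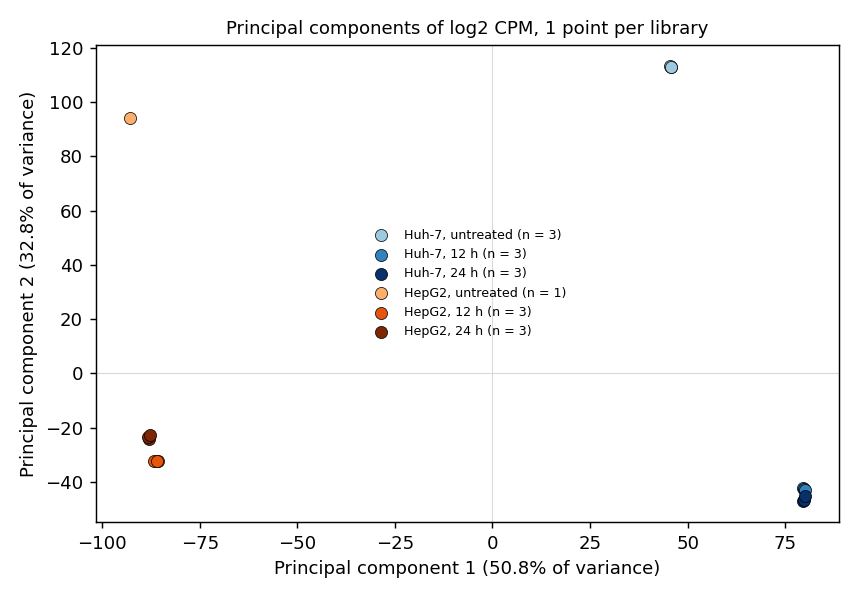
Principal components of log2 CPM, 1 point per library, with the share of variance on each axis. The first component (50.8%) parts Huh-7, between 45.4 and 80.0, from HepG2, between -93.0 and -85.7; the second (32.8%) parts untreated libraries, at 94.0 and above, from treated ones, at -22.6 and below.

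Most transcripts of secreted hepatocyte proteins were near 0 in the untreated libraries of both lines, by CPM without TMM scaling. Alpha-fetoprotein (AFP), the fetal serum protein that hepatomas often make, stood at 0.03 CPM in Huh-7 and was not listed in HepG2. APOA1, the main HDL apolipoprotein, was not listed in either, and APOE, a lipoprotein component made in quantity by liver, stood at 0.10 CPM in Huh-7. Of 28 secreted hepatocyte proteins 19 were listed in at least 1 library, with a median of 0.10 CPM in either line; albumin (ALB) is not analysed here. The exceptions were RBP4, the retinol carrier, at 21.8 and 10.5 CPM, VTN, vitronectin, at 0.86 and 188.3 CPM, and APOM at 3.77 and 10.0 CPM in Huh-7 and HepG2. HNF4A, the nuclear receptor that maintains hepatocyte identity, stood at 37.8 and 0.71 CPM. A list of markers of other cells, fixed beforehand, had medians of 1.75 and 4.91 CPM. It mixes markers of several kinds of cell, so its median says little about any of them. Of its 18 listed members 7 in Huh-7 and 8 in HepG2 stood at 10 CPM or more. Among the 19 secreted hepatocyte proteins 1 and 3 did. The keratins KRT7 and KRT19, whose levels follow, belong to this fixed list too. Among 17 genes chosen after the values were seen, some were abundant and some in 1 line only: the placental alkaline phosphatase ALPP stood at 553.7 and 4483 CPM, the keratins KRT7 at 477.0 and 994.2 CPM and KRT19 at 0.17 and 168.4 CPM, and the folate receptor FOLR1 at 1006 and 9.93 CPM. The same 17 hold enzymes of the urea cycle, a hepatocyte pathway, that were abundant too: CPS1 at 798.2 and 3040.2 CPM and ASS1 at 1991 and 816.6 CPM. The lines are therefore named below as their labels name them.

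**Figure D2:**
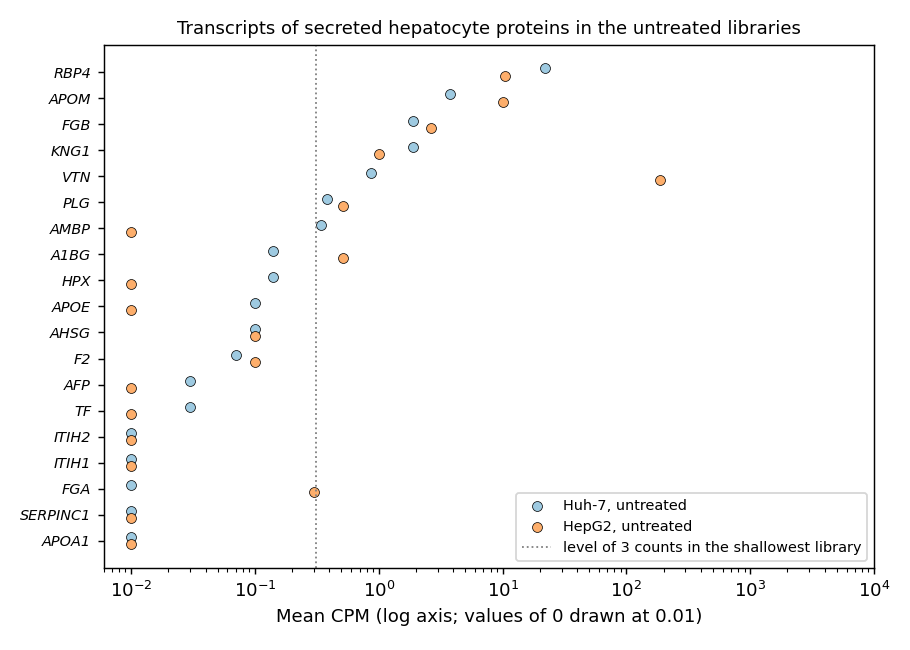
Level in CPM (log axis, 0 drawn at 0.01) of secreted hepatocyte transcripts in untreated Huh-7 (mean of 3 libraries) and untreated HepG2 (1 library), with a dotted line at the level of 3 counts in the shallowest library. RBP4 (21.8 and 10.5) and, in HepG2, VTN (188.3) and APOM (10.0) stand highest, and AFP (0.03 and 0) and APOA1 (0 in both) stand at or near 0.

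In the Huh-7 libraries, 12 h of cinobufagin raised 27 of 28 immediate early genes, whose transcription starts within minutes of a stimulus (median log2 change 3.12, camera adjusted p = 1.83e-45, and 0.00103 with an estimated correlation). EGR1, a zinc finger transcription factor, rose 179-fold from 3.20 ± 0.82 to 576.72 ± 26.96 CPM (log2 7.49, SE 0.077, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 1.27e-61), and the AP-1 subunits FOS and FOSB rose 137-fold and 53.4-fold. Among genes with a mean of at least 10 CPM the largest rise here, 190-fold, was that of HSPA6, a stress-inducible HSP70 chaperone, and MAFF, a small MAF transcription factor, and IL1RL1, the IL-33 receptor, rose 65.8-fold and 54.6-fold. The largest falls among such genes were those of BTN3A3, a butyrophilin (98.1-fold), SCARA5, a ferritin receptor (92.8-fold), EPS8L3 (86.8-fold), FOXN1, a forkhead factor (84.8-fold), and HNF4A, which went from 30.76 ± 0.21 to 0.60 ± 0.29 CPM. In all, 2287 genes were higher and 3689 lower, of which 595 and 1756 changed at least 4-fold.

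Subunits of the drug's own target rose in Huh-7 at 12 h. ATP1B3 went from 142.31 ± 3.16 to 551.31 ± 7.77 CPM (3.87-fold) and ATP1B1 2.2-fold, while FXYD3, a regulatory subunit, fell. Camera's call for the 7 tested subunits (median log2 change 1.00, adjusted p = 0.0431) was lost, at adjusted p = 0.0904 with an estimated correlation. Osmotic stress genes rose (5 of 11, median 0.70, camera adjusted p = 4.42e-05). SLC38A2, an amino acid carrier that imports sodium, went 11.5-fold from 273.15 ± 8.66 to 3137.35 ± 59.22 CPM, NFAT5, the tonicity-responsive transcription factor, 6.56-fold and the salt-regulated kinase SGK1 4.97-fold, with SMOX and HSPA4L, and the water channel AQP1 fell. Integrated stress response targets, which ATF4 and CHOP induce when translation initiation is restrained, also rose (13 of 21, median 1.45, camera adjusted p = 5.46e-07), led by CHAC1, which degrades glutathione (50.4-fold), STC2, a secreted glycoprotein (18.2-fold), and the stress protein SESN2 (13.9-fold). Of 22 heat shock genes 11 rose (median 0.99, camera adjusted p = 1.14e-05), among them the co-chaperone DNAJB1 (5.34-fold), HSPA1A (4.18-fold; its reads are hard to part from those of its twin HSPA1B) and CHORDC1 (4.12-fold). NF-kB targets and cytokines rose (14 of 24, median 1.22, camera adjusted p = 3.86e-05): IL6 went from 1.06 ± 0.33 to 57.60 ± 2.47 CPM, the NF-kB feedback inhibitor TNFAIP3 rose 25-fold and the cytokine IL11 21.8-fold, and TRAF1 fell.

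Cell cycle genes split in Huh-7 at 12 h. Of 30 mitotic genes 10 fell and KIF23 rose (median -0.56, camera adjusted p = 0.00733, lost at adjusted p = 0.194 with an estimated correlation). The hyaluronan receptor HMMR fell 32.7-fold, the mitotic kinesin KIF20A 17.3-fold from 161.25 ± 4.50 to 9.32 ± 1.22 CPM, and the kinases PLK1 and AURKA 5.17-fold and 2.15-fold. Cyclin B1 (CCNB1, log2 -0.58) and its kinase CDK1 (-0.36) missed the fold threshold. DNA replication genes rose (16 of 32, median 1.00, camera adjusted p = 3.83e-07), with the G1/S factor E2F1 4.94-fold, the replication licensing factor CDC6 4.18-fold and the helicase subunit GINS2 4.01-fold higher, and GINS1 and POLA2 lower. Histone genes rose (14 of 17, median 3.17, camera adjusted p = 1.01e-08); most encode replication-dependent histones, whose mRNAs normally end in a stem-loop without a poly(A) tail, in libraries built by oligo-dT capture. H2AC18, identical in all values to H2AC19 and so not separable from it, went from 4.68 ± 0.32 to 163.70 ± 8.60 CPM (34.9-fold), H2BC21 10.9-fold and the linker histone H1-2 10.4-fold. Of 20 homologous recombination and checkpoint genes 8 fell, among them the kinase ATR (4.77-fold), BRCA1 (4.43-fold) and NBN (3.68-fold), and EXO1 and FANCA rose, but the list did not pass (camera adjusted p = 0.174). The p53 targets moved both ways, with 7 of 21 higher, such as the BH3-only killer PMAIP1 (14.6-fold), the CDK inhibitor CDKN1A (12.3-fold) and the kinase PLK3 (10.9-fold), and 7 lower, such as XPC and FAS. Camera's call (adjusted p = 0.0418) was lost, at adjusted p = 0.0904 with an estimated correlation, and the median, 0.14, turned to -0.28 with plain library size and -0.133 with upper-quartile scaling.

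Targets of SRF and YAP, transcription factors tied to the actin cytoskeleton, rose in Huh-7 at 12 h (9 of 17, median 1.01, camera adjusted p = 2.92e-14): the matricellular proteins CCN2 and THBS1 rose 44.6-fold and 39.8-fold and the kinase LATS2 15.9-fold, while ACTA2 fell. Autophagy and lysosome genes rose (9 of 22, median 0.49, camera adjusted p = 0.000129), with the autophagosome protein MAP1LC3B 7.79-fold, the proton pump subunit ATP6V0D1 5.18-fold and ATG12 4.06-fold higher, and TFEB and CTSL lower. Ribosome biogenesis genes rose (10 of 28, median 0.78, camera adjusted p = 0.00124), among them RRP12 (5.32-fold), BYSL (3.46-fold) and the RNA polymerase I factor RRN3 (3.06-fold), with WDR12 lower. Cholesterol synthesis genes fell (8 of 24, median -0.67, camera adjusted p = 0.00888), led by mevalonate kinase MVK (10.9-fold), HSD17B7 (6.85-fold) and squalene epoxidase SQLE (4.49-fold). HMGCS1, which makes HMG-CoA, rose.

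The other lists did not pass in Huh-7 at 12 h. Hypoxia and glycolysis genes (camera adjusted p = 0.253) had 6 of 27 members higher, such as the vasodilator peptide ADM (9.0-fold), the angiogenic factor VEGFA (5.47-fold) and the glucose carrier SLC2A1 (3.86-fold), and CA9, EGLN3, ALDOC, PFKL and ENO2 lower. Interferon response genes (0.124) had 8 of 17 lower, such as OAS1, a double-stranded RNA sensor (21.4-fold), with RSAD2 higher. Among NRF2 targets and metallothioneins (0.164) 7 of 20 fell, MT1E 5.85-fold, the exporter ABCC3 4.27-fold and AKR1C1 3.28-fold. Liver transcription factors (0.271) had 6 of 15 lower, CEBPA 5.97-fold, and NR2F2 (2.39-fold) and NR5A2 higher. Gluconeogenesis and urea cycle genes (0.271) had 5 of 14 lower, argininosuccinate synthase ASS1 2.52-fold and argininosuccinate lyase ASL 2.27-fold with NAGS, HPD and PCK2, while the coactivator PPARGC1A rose 5.74-fold. The mTOR and eIF4E pathway (0.528) had MTOR itself 2.63-fold lower, the kinase MKNK1 4.51-fold and the translation inhibitor PDCD4 3.83-fold lower with 3 more. The cap-binding protein EIF4E was 2.47-fold and S6 kinase RPS6KB1 2.65-fold higher, with TSC1 and RICTOR, and EIF4EBP1 stood at 105.37 against 74.62 CPM. In the Wnt list (0.119) the inhibitor DKK1 rose 45.8-fold and TBX3 3.76-fold with BMP4, and GLUL fell 2.52-fold with LEF1. The endoplasmic reticulum chaperone list (0.141) had 5 of 18 higher, HERPUD1 6.44-fold and DNAJB9 4.78-fold the most, with DNAJB11 (2.96-fold), DNAJC3 and HSPA5, and PDIA4 and SEL1L lower. In the BCL2 family (0.846) the survival protein BCL2L1 rose 4.34-fold with HRK, and BCL2L13 fell 5.03-fold with BMF. Only 3 of 18 snoRNA host genes were tested (0.215), with TAF1D 3.64-fold higher. Among nuclear oxidative phosphorylation genes (0.155) few were called, such as NDUFB10 (2.99-fold lower) and NDUFS1 (2.66-fold lower). Calls were few among acute phase genes (0.469), where CP and ITIH4 were lower. They were few too among secreted hepatocyte proteins (0.846; APOE and FGB higher at under 4 CPM) and markers of other cells (0.402; EPCAM 2.4-fold lower, with VWF, PDGFRB and DCN lower and CD14 higher at low levels). The 72 cytosolic ribosomal protein genes had a median of 0.18, which turned to -0.233 with plain library size and -0.087 with upper-quartile scaling (camera adjusted p = 0.484). Among the fixed genes MYC rose 2.33-fold to 1185 ± 38.23 CPM and ATF3, a stress-induced transcription factor, 30.9-fold. The share of higher genes among those called, 38.3%, was 26.7% with upper-quartile and 21.2% with plain library-size scaling, and 47.3% with division by the library median.

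After 24 h of cinobufagin the Huh-7 libraries still carried high immediate early, histone, replication and autophagy transcripts. Among genes with a mean of at least 10 CPM the largest rises were those of AREG, an EGF receptor ligand (46.8-fold), DLX2, a homeobox factor (45.6-fold), H2AC18 with its twin H2AC19 (39.7-fold, to 186.35 ± 15.68 CPM) and MAFF (34.7-fold). The largest falls among them were those of SCARA5, from 32.61 ± 1.24 to 0.07 ± 0.12 CPM, BTN3A3, from 27.09 ± 1.16 to 0.14 ± 0.24 CPM, EPS8L3 (133-fold), HNF4A (107-fold, to 0.28 ± 0.12 CPM) and LRRC45 (99.0-fold). In all, 2431 genes were higher and 3652 lower than in untreated cells, 541 and 1905 of them at least 4-fold. Relative to untreated cells ATP1B3 was 5.56-fold higher at 790.73 ± 19.69 CPM, with FXYD3 lower (7 Na,K-ATPase subunits, median 0.78, camera adjusted p = 0.0119).

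Of 28 immediate early genes 21 were higher in Huh-7 at 24 h (median 2.45, camera adjusted p = 4.22e-18), led by the AP-1 subunits FOSL1 (21.8-fold) and JUN (20.9-fold) and by PPP1R15A (19.0-fold), which steers the eIF2 phosphatase. Histone genes were higher (15 of 17, median 2.98, camera adjusted p = 7.3e-10), H1-2 18.2-fold and H2BC12 17-fold. So were DNA replication genes (13 of 32, median 0.87, camera adjusted p = 6.82e-05), E2F1 5.84-fold and thymidine kinase TK1 3.53-fold, with POLA2 lower. Of 30 mitotic genes 6 were lower, KIF20A 16-fold, HMMR 15.4-fold, PLK1 3.85-fold and AURKA 3.29-fold with CENPA and CENPE, and NUSAP1 was higher (camera adjusted p = 0.118). CDK1 stood at 49.31 ± 2.97 against 42.59 ± 1.53 CPM. Autophagy and lysosome genes were higher (13 of 22, median 1.21, camera adjusted p = 7.76e-10): the lysosomal calcium channel MCOLN1 went from 26.83 ± 0.80 to 285.43 ± 20.54 CPM (10.6-fold), MAP1LC3B and ATP6V0D1 were 9.19-fold higher, and the protease CTSL was lower. Ribosome biogenesis genes (14 of 28 higher, median 0.98, camera adjusted p = 0.000105) passed as well, and so did NF-kB targets and cytokines (13 of 24 higher, median 1.19, camera adjusted p = 0.000741), with IL11 18.3-fold and RELB 5.69-fold higher. Of 17 SRF and YAP targets 8 were higher, THBS1 20.7-fold and CCN1 6.74-fold, and ACTA2 and ACTB lower (median 0.63, camera adjusted p = 3.2e-05). Cholesterol synthesis genes were lower (10 of 24, median -0.87, camera adjusted p = 0.000733), farnesyl diphosphate synthase FDPS 6.69-fold from 248.19 ± 9.31 to 37.08 ± 1.11 CPM, with SREBF2, a regulator of this pathway, among the higher ones.

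The integrated stress response moved both ways in Huh-7 at 24 h: 11 of 21 targets were higher, such as STC2 (9.9-fold) and the cytokine GDF15 (7.89-fold), and DDIT4, an mTORC1 inhibitor, fell 5.83-fold with TRIB3 and SHMT2. The call (median 1.22, camera adjusted p = 0.0391) was lost, at adjusted p = 0.225 with an estimated correlation. Osmotic stress genes (5 of 11 higher, SLC38A2 5.04-fold, with AQP1 and AQP3 lower; median 0.97, camera adjusted p = 0.0101) also lost their call, at adjusted p = 0.0924 with an estimated correlation. Heat shock genes divided evenly (camera adjusted p = 0.69), with the co-chaperones BAG3 2.58-fold and CHORDC1 2.53-fold higher beside DNAJB4, HSPA4 and DNAJB6, and the constitutive chaperone HSPA8 5.13-fold lower, at 245.75 ± 3.50 against 1261 ± 6.54 CPM, beside HSPA1L, HSPB1, HSP90AA1 and HSPD1. The remaining lists did not pass. Among p53 targets (camera adjusted p = 0.0645) 7 of 21 were higher, PMAIP1 11.4-fold and AEN 8.83-fold, and XPC, FDXR, DDB2, TP53I3 and TP53INP1 lower. Among homologous recombination genes (0.13) 8 of 20 were lower, the MRE11 partner RAD50 9.65-fold. Among NRF2 targets (0.0645) 7 of 20 were lower, AKR1C1 28.5-fold, and FTH1 and OSGIN1 higher. Gluconeogenesis and urea cycle genes (0.0913) had ASS1 7.21-fold lower, at 224.50 ± 12.61 against 1618 ± 41.43 CPM, and PPARGC1A 6.05-fold higher. Hypoxia genes (0.978) had ALDOC 10.3-fold and PFKL 4.76-fold lower beside CA9, EGLN3 and PFKP, and ADM 8.44-fold higher beside SLC2A1 and VEGFA. Interferon genes (0.172) had OAS1 27.3-fold lower and IRF1 2.22-fold higher. The mTOR list (0.449) had 10 of 26 lower, MTOR 2.13-fold, with TSC1 3.28-fold higher. Ribosomal protein genes had members such as RPL36 and RPL19 lower, by 2.46-fold and 2.26-fold, and oxidative phosphorylation genes members such as NDUFB10 and SDHC, by 5.27-fold and 3.52-fold, beside ATP5F1C and NDUFB3. DKK1 (16-fold), CCND1 (3.2-fold), TBX3 and, at about 1 CPM, BMP4 were the higher Wnt targets, CEBPA (5.07-fold) fell most after HNF4A among liver factors, and KRT7 (2.28-fold) was the most abundant of 7 lower markers of other cells. The share of higher genes, 40%, was 27% with upper-quartile and 24.2% with plain library-size scaling, and 44.8% with division by the library median.

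Between 12 and 24 h in Huh-7, heat shock, immediate early and stress response transcripts fell, and autophagy and lysosome transcripts rose. HSPA6 fell 18.7-fold to 5.20 ± 0.74 CPM, EGR1 16.4-fold to 35.26 ± 3.24 CPM, CHAC1 14.1-fold, LURAP1L 13.9-fold and the orphan nuclear receptor NR4A3 11.4-fold. ANGPTL4, an inhibitor of lipoprotein lipase, rose 18.8-fold from 2.19 ± 0.48 to 41.29 ± 2.00 CPM, and PDK4, which shuts pyruvate out of the citric acid cycle, rose 12.2-fold, beside EEFSEC, the selenocysteine elongation factor (7.12-fold), and ELP4 (7.07-fold). In all, 886 genes were higher and 889 lower at 24 h. The share of higher genes, 49.9%, was 57% with plain library-size scaling and 40.4% with division by the library median. Heat shock genes fell (9 of 22, among them DNAJB1, HSPA8 and HSP90AA1, median -0.78, camera adjusted p = 5.83e-26, and 0.00154 with an estimated correlation). Immediate early genes fell as well (12 of 28, with BTG2 higher, median -0.76, camera adjusted p = 8.4e-34, and 0.0019 with an estimated correlation). So did integrated stress response targets (CHAC1, DDIT4, SESN2, SLC7A11, TRIB3 and DDIT3; median -0.44, camera adjusted p = 2.38e-09) and SRF and YAP targets (6 of 17, among them CCN2 and AMOTL2; median -0.67, camera adjusted p = 3.28e-15). Autophagy and lysosome genes rose further (median 0.41, camera adjusted p = 2.15e-06): WIPI1, TFEB, the master regulator of lysosomal genes, MCOLN1 and LAMP2 were higher and CTSL lower. Calls for hypoxia (0.022), osmotic stress (0.00479) and cytosolic ribosomal protein genes (0.0167) were lost, at adjusted p = 0.0807, 0.0807 and 0.773 with an estimated correlation. The other 22 lists had camera adjusted p-values from 0.0519 to 0.979.

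In the HepG2 libraries, 12 h of cinobufagin raised cytokines, immediate early genes and cytoskeleton-linked genes. IL6 went from 1.38 to 301.58 ± 5.24 CPM (216-fold, log2 7.76, SE 0.138, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 2.74e-50), the MAP kinase phosphatase DUSP4 rose 52.2-fold, ANKRD1, a cardiac ankyrin repeat protein, 42.7-fold and THBS1 38.5-fold. RBM14-RBM4 is a read-through transcript whose reads overlap those of RBM14 and RBM4, so its level is uncertain. It stood at 19.42 ± 3.69 CPM and had no count in the untreated library. Counting error alone would put it at least 74.9-fold higher. Its level also varied between libraries of a group, with 1.49, 1.70 and 11.35 CPM in untreated Huh-7, so that bound is not firm. Among genes with a mean of at least 10 CPM over the compared libraries the largest falls were those of TNS2, a focal adhesion protein (35.7-fold), AHNAK2 (31.2-fold), SLFN5 (31.0-fold), the glucose-6-phosphate carrier SLC37A4 (21.1-fold) and the butyrophilin BTN3A1 (20-fold). In all, 1945 genes were higher and 3206 lower, 434 and 1353 of them at least 4-fold, all against 1 untreated library whose spread was assumed.

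Subunits of the Na,K-ATPase rose in HepG2 at 12 h as well. ATP1B1 rose 2.73-fold from 264.43 to 720.65 ± 4.52 CPM and ATP1B3 2.23-fold from 450.74 to 1003 ± 10.46 CPM. The list's call (median 0.18, camera adjusted p = 0.0404) was lost, at adjusted p = 0.0943 with an estimated correlation, and its median was -0.221 with plain library-size and -0.003 with upper-quartile scaling. Osmotic stress genes rose (5 of 11, median 0.77, camera adjusted p = 1.14e-07): SGK1 10.6-fold to 1098 ± 7.21 CPM, SLC38A2 9.19-fold, the taurine carrier SLC6A6 4.98-fold, with NFAT5 and HSPA4L, while AQP1 and SLC6A12 fell. Immediate early genes (23 of 28, median 2.35, camera adjusted p = 5.62e-18) were led by the phosphatase DUSP1 (16-fold), JUN (11.3-fold) and NR4A3 (9.19-fold); EGR1 went from 3.80 to 18.66 ± 0.57 CPM (4.89-fold). NF-kB targets and cytokines rose (14 of 24, median 1.78, camera adjusted p = 8.75e-07), TNFAIP3 10.2-fold and the mitochondrial superoxide dismutase SOD2 7.24-fold, with LIF, TRAF1 and CSF1 lower. Interferon response genes fell (9 of 17, median -1.04, camera adjusted p = 0.000321), OASL 9.06-fold, IFIT1 5.2-fold and IFIT3 3.47-fold. SRF and YAP targets rose (9 of 17, median 1.52, camera adjusted p = 8.21e-15), CCN1 36.0-fold to 2176 ± 24.79 CPM, with ACTA2 lower. So did Wnt targets (4 of 12, median 0.56, camera adjusted p = 0.000502): DKK1 38.4-fold, the T-box repressor TBX3 26.5-fold from 47.79 to 1266 ± 26.15 CPM, BMP4 6.02-fold and CCND1, with GLUL and RNF43 lower.

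Integrated stress response targets fell in HepG2 at 12 h (11 of 21, median -1.02, camera adjusted p = 1.1e-06). DDIT4 fell 11.6-fold from 625.90 to 54.00 ± 0.87 CPM, the pseudokinase TRIB3 7.79-fold from 223.98 to 28.74 ± 1.46 CPM and CHAC1 4.59-fold from 51.50 to 11.21 ± 0.47 CPM, while SLC3A2 rose. The lone untreated HepG2 library stood above the untreated Huh-7 libraries for these genes, by a median log2 of 1.45 over the 21 genes, with DDIT4 at 315.49, TRIB3 at 82.15 and CHAC1 at 2.73 CPM in Huh-7. DNA replication genes rose (13 of 32, median 0.80, camera adjusted p = 7.28e-07), with cyclin CCNE2 3.94-fold and the ribonucleotide reductase subunit RRM2 3.4-fold higher. Of 30 mitotic genes 7 rose, ASPM 4.76-fold and CDK1 3.01-fold from 21.09 to 63.49 ± 1.15 CPM, and CDC25C (2.95-fold) and HMMR fell. The call (median 0.40, camera adjusted p = 0.0195) was lost, at adjusted p = 0.247 with an estimated correlation. AURKA stood at 117.35 ± 2.45 against 89.96 CPM. Of 17 histone genes 9 rose, H2AX 4.42-fold, H2BC12 3.74-fold and H2AC18 2.52-fold, but the call (median 1.24, camera adjusted p = 0.00681) was lost, at adjusted p = 0.123 with an estimated correlation. Ribosome biogenesis genes rose (12 of 28, median 0.93, camera adjusted p = 1.72e-06), the snoRNP proteins NOP56 and NOP58 4.04-fold and 3.91-fold, with WDR12 lower. So did autophagy and lysosome genes (10 of 22, median 0.58, camera adjusted p = 0.000321), GABARAPL1 5.79-fold, with WIPI1 and TFEB lower.

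Heat shock genes (8 of 22 higher, DNAJA1 3.88-fold, HSPA4L 3.27-fold and HSPA8 2.85-fold, with HSPA1L and CRYAB lower; median 0.75, camera adjusted p = 0.000596) lost their call in HepG2 at 12 h, at adjusted p = 0.0943 with an estimated correlation. So did hypoxia genes (ADM 14-fold, the stress-responsive NDRG1 7.48-fold and PGAM1 2.22-fold higher with ANKRD37 and SLC2A1, CA9 and EGLN3 lower; median 0.26, which was -0.14 with plain library-size scaling; camera adjusted p = 0.0195), at adjusted p = 0.0635 with an estimated correlation. The remaining lists did not pass. Cholesterol synthesis genes went both ways (camera adjusted p = 0.768), with TMEM97, SC5D and HMGCS1 among the higher ones and HSD17B7 (4.26-fold), MVK (3.35-fold), FDFT1 and SQLE lower. Gluconeogenesis and urea cycle genes (0.114) had mitochondrial PEP carboxykinase PCK2 8.09-fold lower beside ASL (2.68-fold), NAGS and FBP1, and PPARGC1A 5.84-fold higher. Of 15 liver transcription factors (0.14) 7 fell, the pioneer factor FOXA1 2.11-fold, and acute phase genes (0.136) had CFB 2.55-fold and CP 2.39-fold lower beside ITIH4 and C4BPA. Among p53 targets AEN (4.33-fold), PMAIP1 (3.75-fold), CDKN1A (3.0-fold), GADD45A and TNFRSF10B were higher and 6 lower, led by the repair factor XPC (6.92-fold); BRCA1 (3.05-fold), ATR (2.57-fold), PALB2 (2.5-fold), FANCD2 and NBN fell among recombination genes. In the mTOR list the kinases MKNK2 and ULK1 fell 5.84-fold and 5.15-fold and MTOR 2.31-fold with 4 more, and RICTOR rose 4.25-fold and EIF4E 2.1-fold with EIF4EBP2, RPS6KB1 and TSC1. The ferritin subunit FTH1 rose 3.06-fold to 15848 ± 52.82 CPM and thioredoxin reductase TXNRD1 2.21-fold with TXN, and MT1E, MT1X, ABCC3 and AKR1C1 fell. MYC rose 3.64-fold to 803.23 ± 18.79 CPM, BCL2L1 2.02-fold with HRK, and TAF1D 3.93-fold with RC3H2, and BCL2L13 fell 4.03-fold with BMF, and NDUFB10 4.11-fold. DNAJB9 was the 1 chaperone of the endoplasmic reticulum called (2.52-fold higher) and APOE the 1 secreted hepatocyte protein, at about 1 CPM. Of the markers of other cells CDH5 (2.07-fold) and CD14 were higher and DCN, COL1A1 and PDGFRB lower. The share of higher genes, 37.8%, was 19.2% with plain library-size scaling and 49.4% with division by the library median.

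After 24 h the HepG2 libraries kept high IL6 and had lower interferon response transcripts than the untreated library. IL6 stood at 182.57 ± 4.26 CPM (131-fold), and the pregnancy-specific glycoproteins PSG5 and PSG4, near-identical genes whose reads are hard to part, stood at 24.20 ± 1.25 and 26.47 ± 0.95 CPM against 0.17 and 0.26 CPM. NKD2, an antagonist of Wnt signalling, was 27.5-fold and DUSP4 23.7-fold higher, and TNS2 (35.6-fold), the mitochondrial NLRX1 (32.7-fold), the sodium chloride carrier SLC12A3 (27.1-fold), LXN (25.1-fold) and the gel-forming mucin MUC5AC (23.5-fold) fell most among genes with a mean of at least 10 CPM. In all, 1916 genes were higher and 3030 lower, 353 and 1412 of them at least 4-fold. ATP1B1 was 3.59-fold and ATP1B3 2.98-fold higher, and FXYD3 lower. Over the 7 subunits the median was -0.01 and 0.114 with division by the library median, while the mean was 0.203 and camera's test pointed up (adjusted p = 0.013).

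Of 17 interferon response genes 12 were lower in HepG2 at 24 h (median -1.62, camera adjusted p = 1.19e-05), OASL 11.1-fold from 167.47 to 15.12 ± 0.40 CPM, OAS1 9.95-fold and IFIT1 5.57-fold. Acute phase genes (6 of 8 lower, CFB 3.6-fold, CP 3.33-fold and complement C3 2.22-fold; median -1.44, camera adjusted p = 0.0174) lost their call, at adjusted p = 0.0569 with an estimated correlation. Gluconeogenesis and urea cycle genes (camera adjusted p = 0.027) lost theirs too, at adjusted p = 0.0633 with an estimated correlation. There ASL was 8.15-fold, HPD 7.45-fold and PCK2 5.71-fold lower with FBP1 and NAGS, and PPARGC1A higher. Immediate early genes (17 of 28 higher, median 1.40, camera adjusted p = 2.57e-08) were led by DUSP1 (9.02-fold), JUN (7.45-fold) and FOSL1 (5.54-fold), while EGR1, at 3.88 ± 0.78 CPM, was back at its untreated level of 3.80. Of 11 osmotic stress genes 6 were higher, SGK1 10.0-fold and SLC38A2 7.67-fold (median 1.13, camera adjusted p = 5.58e-07). Of 17 SRF and YAP targets 9 were higher, CCN1 21.6-fold and AMOTL2 6.5-fold, and ACTA2 lower (median 1.34, camera adjusted p = 7.67e-08). NF-kB targets and cytokines were higher (12 of 24, median 1.14, camera adjusted p = 0.000479), SOD2 7.3-fold, with TRAF1, LIF and CXCL3 lower. Hypoxia genes passed too (median 0.66, camera adjusted p = 0.00331), with ADM 8.57-fold and NDRG1 8.26-fold higher and PFKL 3.96-fold lower beside CA9 and ALDOC. Ribosome biogenesis genes were higher (15 of 28, median 1.02, camera adjusted p = 6.68e-09), NOP58 4.54-fold and the pseudouridine synthase DKC1 4.09-fold. So were autophagy and lysosome genes (7 of 22, median 0.69, camera adjusted p = 0.000272), MCOLN1 5.15-fold and the lysosomal galactosidase GLA 4.3-fold, with CTSL lower. Among DNA replication genes (median 0.35, camera adjusted p = 0.0141) CCNE2 (3.8-fold), CDC6, UHRF1 and MCM4 were higher and POLA2 lower.

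Several further HepG2 lists at 24 h passed only at the preset correlation. Histone genes (7 of 17 higher, H2BC12 3.69-fold; camera adjusted p = 0.00595) lost their call at adjusted p = 0.0956 with an estimated correlation. Heat shock genes (10 of 22 higher, HSPA8 3.13-fold, with HSPB1 3.77-fold lower beside CRYAB and HSPA1L; 0.000605) lost theirs at adjusted p = 0.0812 with an estimated correlation. Mitotic genes (7 of 30 higher, ASPM 5.5-fold and CDK1 3.07-fold, CDC25C lower; 0.0405) and endoplasmic reticulum chaperones (DNAJC3, DNAJB9 and HERPUD1 higher, PDIA4 lower; 0.0334) stood at adjusted p = 0.295 and 0.112 with an estimated correlation. Wnt targets (TBX3 9.29-fold, DKK1 8.67-fold, CCND1 7.69-fold and BMP4 higher, RNF43 lower; 0.0137) stood at adjusted p = 0.0656 with an estimated correlation. Markers of other cells (DCN 3.94-fold, COL1A1 3.84-fold and KRT19 2.51-fold lower with PDGFRB and KRT7, CD14 higher; 0.0405) stood at adjusted p = 0.0889 with an estimated correlation. Stress response targets (camera adjusted p = 0.0722) had STC2 3.8-fold and SLC3A2 3.75-fold higher and 6 of 21 lower, WARS1 3.58-fold. Cholesterol synthesis genes (0.474) had MVK 6.4-fold and FDFT1 3.07-fold lower beside HSD17B7, FDPS and MVD, and SC5D 2.78-fold higher beside TMEM97 and HMGCS1. Among p53 targets (0.168) AEN was 5.82-fold higher and FDXR, TP53I3, DDB2 and XPC lower. Among NRF2 targets AKR1C1 was 5.97-fold lower and OSGIN1 5.03-fold and FTH1 3.44-fold higher. RICTOR was 4.62-fold higher and ULK1 3.47-fold and TSC2 2.88-fold lower. NDUFB10, NDUFV1 and NDUFB3 among oxidative phosphorylation genes, RPL12 (2.34-fold), RPL36, RPS18 and RPS4X among ribosomal protein genes, NBN and FANCD2 among recombination genes, and FOXA1 (3.42-fold), HNF4A and CEBPA among liver factors were lower. The untreated library held only 0.60 CPM of HNF4A and 4.06 CPM of CEBPA. TAF1D, ONECUT2, APOE, BNIP3L and HRK were higher, and BCL2L13 and BMF lower. AURKA (108.31 ± 6.69 against 89.96 CPM) and CCNB1 (119.71 ± 1.86 against 128.67 CPM) were not called. The share of higher genes, 38.7%, was 24.1% with plain library-size scaling and 46% with division by the library median.

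Between 12 and 24 h in HepG2, integrated stress response targets rose and immediate early genes fell. DDIT4 rose 6.06-fold from 54.00 ± 0.87 to 327.16 ± 18.69 CPM, together with STC2, CHAC1, ASNS, VLDLR, TRIB3 and SESN2 (7 of 21 higher, median 0.45, camera adjusted p = 1.14e-09). Other large rises were those of SLFN5 (13.8-fold), HES7 (6.37-fold) and PSG5 (6.11-fold). Among genes with a mean of at least 10 CPM the largest falls were those of DLX2 (8.1-fold), TENT5B (5.89-fold), SELENBP1, a selenium-binding protein (5.31-fold), CDK5 (5.16-fold) and LOC102724594, which varied widely between libraries (4.46 ± 3.72 against 27.90 ± 13.72 CPM). In all, 888 genes were higher and 723 lower, and the share of higher genes, 55.1%, was 67.4% with plain library-size scaling and 46.7%, a majority of lower genes, with division by the library median. Immediate early genes (8 of 28, EGR1 4.8-fold; median -0.74, camera adjusted p = 9.75e-14) and SRF and YAP targets (THBS1 4.07-fold, LATS2 and CCN2; median -0.56, camera adjusted p = 1.29e-10) fell. So did NF-kB targets (CXCL8, RELB and TRAF1; median -0.69, camera adjusted p = 0.000775) and DNA replication genes (MCM5; median -0.36, camera adjusted p = 2.65e-08). Calls for liver transcription factors (0.0214), cholesterol synthesis genes (0.0323), ribosomal protein genes (1.02e-05), Wnt targets (0.00322) and markers of other cells (0.0401) were lost, at adjusted p = 0.158, 0.0716, 0.41, 0.0631 and 0.12 with an estimated correlation. The other 20 lists had camera adjusted p-values from 0.0633 to 0.985.

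**Figure D3:**
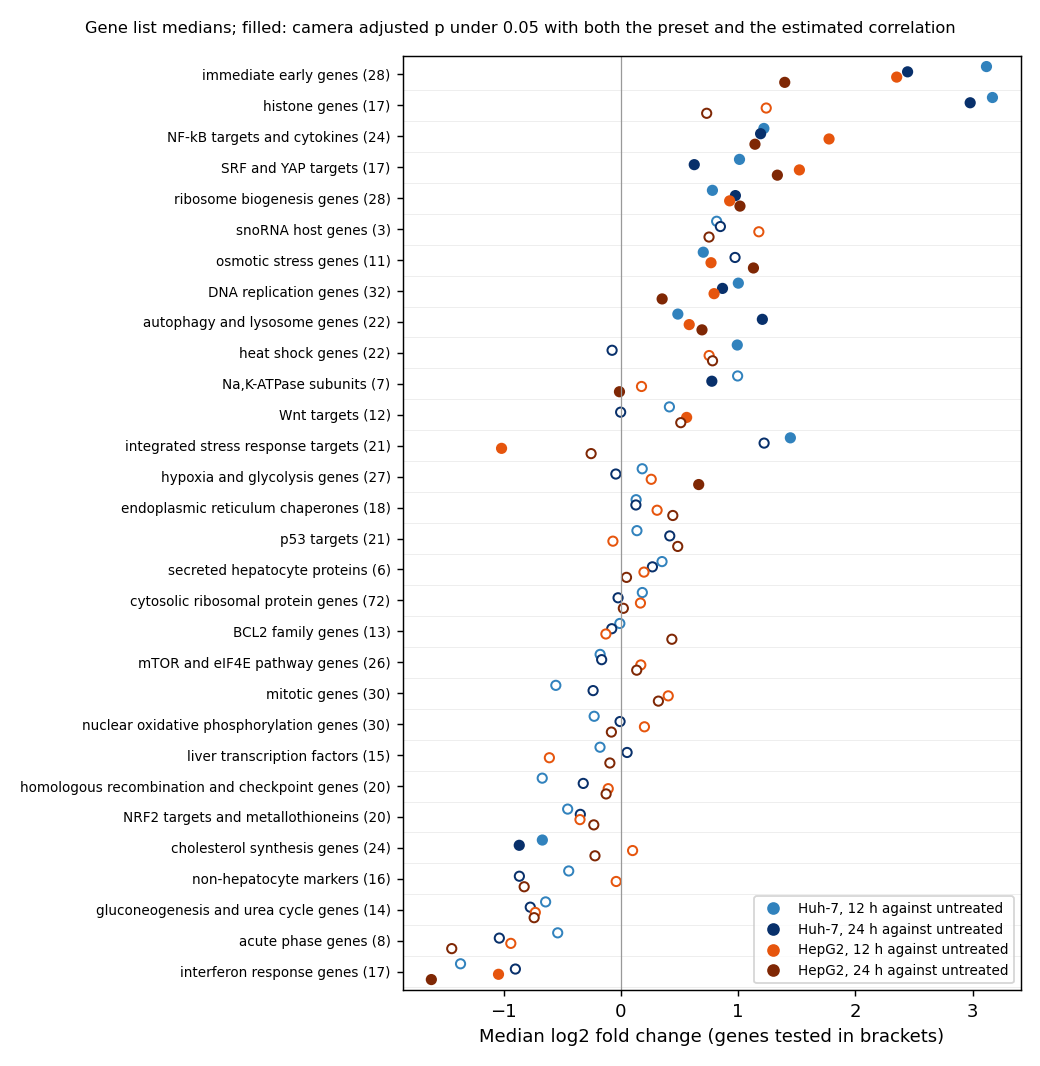
Median log2 fold change of each gene list against untreated cells, with the number of tested genes in brackets; filled points passed camera with both the preset and the estimated correlation. Immediate early genes stand at 3.12 and 2.45 in Huh-7 and 2.35 and 1.40 in HepG2 at 12 and 24 h, and integrated stress response targets at 1.45 in Huh-7 and -1.02 in HepG2 at 12 h; some small medians change sign with the scaling (p53 targets in Huh-7 at 12 h, 0.14, stood at -0.28 with plain library size).

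**Figure D4:**
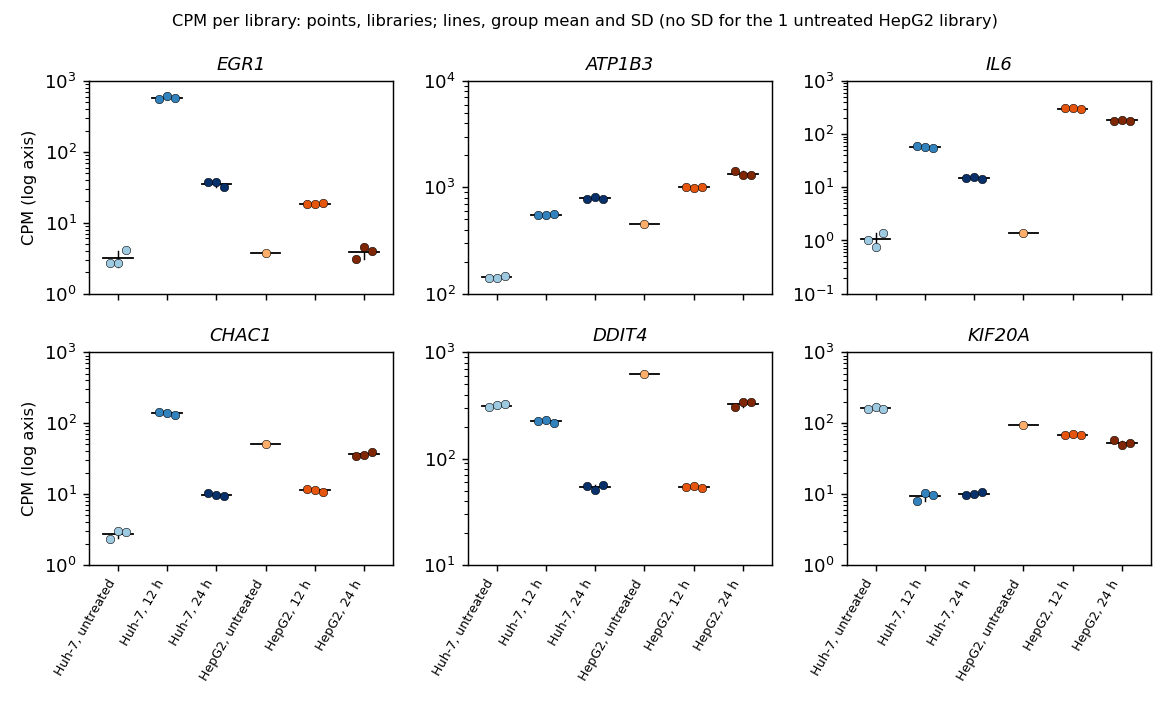
Level of 6 genes per library (log axis), with lines at the group mean and SD. CHAC1 goes from 2.73 over 138.3 to 9.82 CPM in Huh-7 and from 51.5 over 11.2 to 36.1 CPM in HepG2 at 0, 12 and 24 h, and ATP1B3 rises from 142.3 to 790.7 CPM in Huh-7 and from 450.7 to 1344 CPM in HepG2 at 24 h.

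The responses of the lines overlapped. At 12 h, 1251 genes were higher in both lines, where independent lists of those sizes would share 326.3, and 2368 were lower in both, against 867.5; 57 genes moved in opposite directions. At 24 h the counts were 1087 against 341.7, 2185 against 811.7, and 86. Across the 13633 genes, which are not independent replicates, the log2 changes of the lines correlated at r = 0.704 (Spearman 0.744) at 12 h and 0.661 (0.68) at 24 h; no libraries are shared between the lines. ATP1B3, the immediate early genes JUN and DUSP1, the cytokine IL6 and the lysosomal genes MCOLN1 and GABARAPL1 were called higher in both lines at both times, and the enzymes MVK and HSD17B7, OAS1, HNF4A and CEBPA lower. In HepG2, HNF4A started from only 0.60 CPM, close to the level of 3 counts, and CEBPA from 4.06 CPM, each in 1 untreated library.

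At 12 h the change in HepG2 differed from that in Huh-7 for 2428 genes, 1287 with the higher log2 change in HepG2 and 1141 with the lower. The integrated stress response differed most: 16 of 21 targets had the lower change in HepG2 (median difference -1.86, camera adjusted p = 4.98e-59). CHAC1 stood at -7.86 (SE 0.150, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 1.46e-47), the transcription factor DDIT3 at -4.76, STC2 and SESN2 at -4.74 and ASNS, asparagine synthetase, at -3.28. The untreated HepG2 library already held 51.50 CPM of CHAC1 against 2.73 CPM in Huh-7, and 223.98 CPM of TRIB3 against 82.15. Mitotic genes had the higher change in HepG2 (19 of 30, median difference 1.11, camera adjusted p = 6.46e-19): HMMR 3.92, KIF20A 3.63, CENPE 2.92, PLK1 2.63, CDK1 1.95, AURKA 1.49 and CCNB1 1.03. Histone genes had the lower change (11 of 17, median difference -1.63, camera adjusted p = 2.03e-11), H2AC18 -3.79 and H1-2 -2.73. The untreated levels differed here too. Summed over 63 clustered histone genes, the lone untreated HepG2 library stood at 521.6 CPM against 95.5 in Huh-7. At 12 h the sums were 1317 and 1136 CPM. Cholesterol synthesis genes had the higher change in HepG2 (SC5D 2.48, MVK 1.70, TMEM97 1.57, IDI1, LSS, NSDHL and FDPS, with a median difference of 0.64 and camera adjusted p = 1.42e-07). Immediate early genes were lower in HepG2 for 11 of 28 (EGR1 -5.20, FOS -4.78, ATF3 -3.51), a call (camera adjusted p = 5.69e-08) that was lost at adjusted p = 0.11 with an estimated correlation. IL6 rose more in HepG2 (2.01). The other genes at the ends of the ranking had a group near 0 counts, and their levels at 0, 12 and 24 h say more than a fold. NOTCH3 stood at 253.8, 46.26 and 19.02 CPM in Huh-7 and 0, 0.33 and 0.20 CPM in HepG2, and PLIN2, a lipid droplet protein, at 22.17, 33.69 and 98.66 against 0, 0.49 and 0.23 CPM. PCSK1, a prohormone convertase, stood at 5.99, 0.04 and 0.28 against 48.48, 12.47 and 5.82 CPM, and HSPA6 and IL1RL1 were near 0 in HepG2. The other 25 lists had camera adjusted p-values from 0.134 to 0.928.

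At 24 h the lines differed for 3258 genes, 1782 with the higher change in HepG2 and 1476 with the lower; 54.7% were higher, and 65.4% with upper-quartile scaling. Integrated stress response targets (11 of 21 lower in HepG2, DDIT4 higher; median difference -1.38, camera adjusted p = 3.11e-08) were led by GDF15 at -4.13, which went from 8.30 to 65.57 CPM in Huh-7 and from 62.56 to 28.24 CPM in HepG2. Histone genes had the lower change in HepG2 (12 of 17, median difference -1.98, camera adjusted p = 2.83e-10). The summed clustered histone genes stood at 1194 CPM in HepG2 and 1423 in Huh-7 at 24 h, against 521.6 and 95.5 CPM untreated. Autophagy and lysosome genes had the lower change too (7 of 22, median difference -0.51, camera adjusted p = 9.71e-05), MAP1LC3B -1.76, ATP6V0D1 -1.73 and MCOLN1 -1.05. DNA replication genes had it too (median difference -0.31, camera adjusted p = 0.00164), E2F1 at -2.38 with MCM5, TK1, CCNE1 and CDC45 lower, and CCNE2 and UHRF1 higher. Mitotic genes had the higher change (11 of 30, median difference 0.66, camera adjusted p = 1.53e-07), KIF20A 3.14 and AURKA 1.99. So did heat shock genes (median difference 0.47, camera adjusted p = 1.53e-07), with HSPA8 at 4.01, HSPA1B, HSPA1A, HSPD1 and HSPE1 higher and BAG3 lower. Hypoxia genes (NDRG1 3.28, EGLN3, ENO2 1.89, PFKP 1.88, ALDOC 1.64 and BNIP3 1.17; median difference 0.51, camera adjusted p = 5.92e-05) and cholesterol synthesis genes (6 of 24 higher, median difference 0.50, camera adjusted p = 0.000212) had it as well. Calls for immediate early genes (0.000605), NRF2 targets (0.0248) and osmotic stress genes (0.00818) were lost, at adjusted p = 0.237, 0.0579 and 0.0708 with an estimated correlation. Of the genes at the ends of the ranking, IGFN1 and HOXB9 rose in HepG2 from 0.09 and 0.17 CPM to 13.19 and 9.50 CPM. The other 19 lists had camera adjusted p-values from 0.051 to 0.978.

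The change from 12 to 24 h, which uses no untreated library, differed between the lines for 1665 genes, 944 higher and 721 lower in HepG2. The integrated stress response again led (11 of 21 targets higher in HepG2, WARS1 lower; median difference 1.02, camera adjusted p = 1.14e-28). CHAC1 fell from 138.27 to 9.82 CPM in Huh-7 and rose from 11.21 to 36.11 CPM in HepG2, a difference of 5.50. DDIT4 fell from 223.38 to 54.07 CPM in Huh-7 and rose from 54.00 to 327.16 CPM in HepG2, a difference of 4.65. Heat shock genes had the higher change in HepG2 (9 of 22, median difference 0.92, camera adjusted p = 1.77e-23), DNAJB1 2.86, HSPA1A 2.67 and HSPA8 2.01. So did hypoxia genes (EGLN3, PDK1, BHLHE40, PFKP and HK2; median difference 0.37, camera adjusted p = 0.00146). Autophagy and lysosome genes (MCOLN1, ATP6V0D1, TFEB and ATG2A; median difference -0.48, camera adjusted p = 8.84e-06) and DNA replication genes (MCM5 and E2F1 lower, UHRF1 higher; median difference -0.30, camera adjusted p = 0.0114) had the lower one. LURAP1L went from 29.85 to 2.14 CPM in Huh-7 and from 5.59 to 12.00 CPM in HepG2, and PDK4 the other way, from 1.92 to 23.64 CPM and from 41.67 to 18.32 CPM. Lower differences were also those of the phospholipase LIPH (-2.91) and of DLX2 (-2.85). Calls for immediate early genes (0.0216), mitotic genes (0.0147) and liver transcription factors (0.0132) were lost, at adjusted p = 0.523, 0.443 and 0.172 with an estimated correlation. The other 22 lists had camera adjusted p-values from 0.0737 to 0.978.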

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

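The line differences of the next paragraph stand out because the change differed between the lines by a direct test of the difference. The tests of depth, of gene models, of the lone untreated HepG2 library, of near-identical histone genes and of S phase were chosen after the results they measure were seen; those of another kind of cell, of the scaling and of other splits of the libraries were written before.

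At 12 h the difference covered 2428 genes. Over the integrated stress response targets its median was -1.86, with CHAC1 at -7.86, over histone genes -1.63, over mitotic genes 1.11 and over cholesterol synthesis genes 0.64. At 24 h it covered 3258 genes, with medians of -1.38 (integrated stress response targets, GDF15 at -4.13), -1.98 (histone genes), -0.51 (autophagy and lysosome genes), -0.31 (DNA replication genes), 0.66 (mitotic genes), 0.50 (cholesterol synthesis genes), 0.51 (hypoxia genes) and 0.47 (heat shock genes). For the change from 12 to 24 h it covered 1665 genes, with medians of 1.02 (integrated stress response targets), 0.92 (heat shock genes), 0.37 (hypoxia genes), -0.48 (autophagy and lysosome genes) and -0.30 (DNA replication genes), and single genes at 5.50 (CHAC1), 4.90 (LURAP1L), 4.65 (DDIT4), -4.80 (PDK4), -2.91 (LIPH) and -2.85 (DLX2). The first 2 of these comparisons rest on 1 untreated HepG2 library.

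Most transcripts of secreted hepatocyte proteins were near 0 in the untreated libraries of both lines. Depth is argued against, since 3 counts amount to at most 0.314 CPM in any library. Absence from the gene models is argued against for the 19 of 28 secreted hepatocyte genes that are listed in at least 1 library. For the 9 listed in none, absence from the models cannot be told apart from a level of 0. A second list of transcripts that hepatocyte-like lines make was fixed before its levels were read. Of its 32 members 20 were listed in at least 1 library. Over these 20 the medians were 0.188 CPM in Huh-7 and 0.10 CPM in HepG2. The members listed in no library were left out. The most abundant member was LIPA (78.3 and 82.8 CPM), a gene made in most cells. The libraries may therefore come from another kind of cell than their labels say; which kind was not tested. Against this stand the urea cycle enzymes CPS1 (798.2 and 3040.2 CPM) and ASS1 (1991 and 816.6 CPM), chosen after the values were seen. So do HNF4A (37.8 CPM) and CEBPA (52.9 CPM) in Huh-7 and VTN (188.3 CPM) in HepG2, picked from the fixed lists. Of 21 listed liver transcription factors, however, 7 in Huh-7 and 8 in HepG2 stood under 1 CPM, while 11 and 8 stood at 10 CPM or more. FOXA3 and ONECUT1 stood at 0 in both lines. These few genes therefore do not settle the question. Loss of hepatocyte expression in culture stays open as well, untested.

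Integrated stress response targets moved apart between the lines at 12 h. The choice of scaling is argued against as the cause: the median line difference was -1.77 or further from 0 under every scaling tried. The lone untreated HepG2 library stays open as a part of the cause. It stood above untreated Huh-7 by a median of 1.45 over the 21 genes (14 higher, 1 lower), and with untreated libraries left out the 12 h libraries of the lines differed by -0.422 (2 higher, 9 lower) and the 24 h libraries by 0.77. A high untreated level could thus account for much of the fall in HepG2, but not for the difference in the change from 12 to 24 h, 1.02, which uses no untreated library, and a true difference between the lines stays open too.

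Histone transcripts rose in Huh-7. A shift of reads between near-identical genes is argued against: the summed level of all clustered histone genes went from 95.5 ± 2.5 CPM to 1136 ± 21.6 at 12 h and 1423 ± 84.6 at 24 h, and the lowest treated library lay 11.3-fold above the highest untreated one. In HepG2 the sum was 521.6 CPM in the lone untreated library, 1317 ± 30.2 at 12 h and 1194 ± 16.1 at 24 h. By this sum the line differences rest largely on the untreated levels, which for HepG2 come from 1 library. More cells in S phase stay open as a cause. The histone median exceeded that of DNA replication genes by 2.11 in Huh-7 at 24 h, where the replication genes rose as well (median 0.87). Histone transcripts may follow S phase more steeply than replication genes do, so this excess cannot decide. Since oligo-dT capture reads histone transcripts mainly where they carry a poly(A) tail, a change in their 3' ends may contribute; it was not tested, and neither was a change in transcription.

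For the comparisons with 3 libraries on each side, 10 splits of the 6 libraries are too few for a share under 0.05. The real splits called 5976 genes (Huh-7 at 12 h), 6083 (Huh-7 at 24 h), 1775 (Huh-7, 24 against 12 h) and 1611 (HepG2, 24 against 12 h), each the highest 1 of its 10, and the highest other split called 0 in each. For the line difference in the change from 12 to 24 h, 2 of 40 splits, the real one included, called at least 1665 genes. The other of these, also at 1665, keeps the real times in Huh-7 and mixes those in HepG2; another, at 1465, keeps those in HepG2 and mixes those in Huh-7. Each holds the whole time effect of 1 line, so neither shows what chance alone gives, and chance is neither excluded nor supported by this count. The remaining splits drawn called 0 genes by edgeR.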

How the results depend on the processing

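The alternatives were fixed beforehand, except an assumed coefficient of variation of 0.2, which was chosen after the data were seen. Of 188 counts of called genes under an alternative, 169 lay within 1.5 times the count reported. Without a fold threshold the counts were 11418 (Huh-7 at 12 h), 11423 (24 h), 8400 (24 against 12 h), 10037 (HepG2 at 12 h), 9994 (24 h), 8411 (24 against 12 h) and 7100, 8197 and 6929 (line differences at 12 h, at 24 h and in 24 against 12 h), because smaller changes then count. Limma on log2(FPKM + 1) gave 721 (Huh-7, 24 against 12 h), 3200 (HepG2 at 24 h), 595 (HepG2, 24 against 12 h) and 1481, 2066 and 809 for the line differences, and without its filter 732, 610 and 827 for the comparisons of 24 with 12 h in Huh-7, in HepG2 and between the lines; the cause was not tested. The assumed variation of 0.2 gave 1600 for the line difference at 12 h.

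Leaving out each library in turn gave 5932 to 5962 and 6011 to 6067 genes for Huh-7 at 12 and 24 h, 1732 to 1756 for 24 against 12 h, 5090 to 5108 and 4901 to 4938 for HepG2, 1572 to 1615 for its 24 against 12 h, and 2407 to 2434, 3154 to 3275 and 1621 to 1668 for the line differences. The lone untreated HepG2 library cannot be left out of its comparisons, so it gives no value there; where a group keeps 1 library, that library is assumed to vary like the others. With the replicate number as a block the counts were 5974, 6082, 1764, 5119, 4919, 1610, 2396, 3233 and 1656. Of 30 pairs of residual profiles with the same number in different groups none correlated above 0.1 (-0.056 to 0.058). No pairing by number was seen. Counting noise in scarce genes, which weigh as much as abundant ones here, could hide one, so pairing is not excluded.

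Of the named genes under an alternative, 8231 values kept direction and side of the threshold, 180 kept the direction but not the call, 30 gained a call and 12 reversed. The reversed values belong to line differences with a group near 0, and a pseudocount outweighs such levels by construction. With log2(FPKM + 1), with or without its filter, the value was -0.969 (Line difference at 24 h: FOXD1), PCSK1 stood at -0.62 at 12 h, ABCB1 at 0.00 and OSBPL7 at 1.41 at 24 h, and TENM3 at 0.19 for 24 against 12 h; with a pseudocount of 0.1 OSBPL7 stood at 0.077 and TENM3 at 0.091. Of counts of called list members, 9864 stayed within 1.5 times the original count and 1416 did not. Of list tests 366 kept their direction and side of the threshold and 33 lost a call with an estimated correlation. Fry passed 141 that camera had not, in the same direction, but it tests a list against no change and camera against all other genes, so these are not the same call gained. Depth limits what can be said of genes under 0.287 to 0.314 CPM, the level of 3 counts.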

Other observations

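The families in this part were chosen after the data were seen. Of 158 groups of genes with a shared symbol stem and at least 10 tested members, 2 passed camera at the preset correlation in all 4 comparisons with untreated cells, aldehyde dehydrogenases and DEAD-box helicases. With an estimated correlation the aldehyde dehydrogenases passed in HepG2 at 24 h and the helicases in none of the 4.

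Aldehyde dehydrogenases (16 genes) were lower for 10 and 11 genes in Huh-7 at 12 and 24 h and for 5 and 10 genes in HepG2, with medians of -1.66, -1.64, -0.78 and -1.39 and adjusted p = 0.142, 0.149, 0.189 and 0.0207 with an estimated correlation. DEAD-box helicases (33 genes) were higher for 8, 13, 9 and 10 genes and lower for 4, 5, 5 and 2 in the same order. Their medians were 0.54, 0.80, 0.67 and 0.70, with camera adjusted p = 0.142, 0.129, 0.189 and 0.157 with an estimated correlation.

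The read-through transcript RBM14-RBM4 stood at 1.49, 1.70 and 11.35 CPM on the TMM scale in the untreated Huh-7 libraries. Fewer genes were listed in treated than in untreated libraries of both lines at similar depth.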
